A study of Nicotiana benthamiana with 8 samples.

How the data were processed

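RNA was sequenced from Nicotiana benthamiana leaves infiltrated with Agrobacterium tumefaciens. Per the labels, the MYB93 group received a strain carrying apple MYB93 (MdMYB93) under the constitutive 35S promoter together with a strain carrying P19, a viral suppressor of gene silencing, and the P19 group received the P19 strain alone. Each group held 4 biological replicates, each a pool of 6 plants, with the first 4 leaves of each plant infiltrated at 3 weeks of age and collected 6 days later. The MYB93 strain was set to an optical density of 0.8 and the P19 strain to 1, so the P19 group received no companion strain with an empty vector and the bacterial dose differed between the groups. Stranded libraries were read as 76 base pair paired ends over 5 MiSeq runs, per the labels' protocols. The labels give no run or library batch per sample.

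The authors deposited 2 count tables. Per the file headers, reads were counted on the 49818 primary transcripts of the N. benthamiana version 5 transcriptome, and the reads left unmapped there were counted on its 184708 secondary transcripts. For each library the deposited tables give counts as unique gene reads, which match a single transcript, and total gene reads, which include reads matching several; the aligner and the rule by which the authors shared such reads are not given in the sources used here. The deposited RPKM of each library (16 columns over both tables) was not used in any test. The authors also deposited a p-value adjusted for false discovery from Baggerley's test, and a selected list with a log2 ratio of RPKM, per the file headers; that list was made with CLC Genomics Workbench 8.01, by thresholds not given in the sources used here, per the file header. Contig size, the length of each transcript, was used as deposited. Gene names are the symbols of the best Arabidopsis match that the deposited tables pair with each transcript, next to 2 descriptions. These at times name another member of the family (among them, the KCS2 transcript is described as KCS19, that of MYB41 as MYB32, those of MYB93 as MYB39 and that of MYB67 as MYB86). Both descriptions of the ABA2 transcript name other enzymes. The LTPG1 transcript has the symbol AT2G44300 and was matched by the LTPG1 locus in its description. An Arabidopsis symbol was given for 44.3% of primary and 72.1% of secondary transcripts. No genome or coordinates were used.

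Total gene reads were the counts of the main test. Library totals in the primary table ranged from 15348450 to 22351974 reads and in the secondary table from 2485610 to 3772692. Transcripts were filtered with filterByExpr, scaled by TMM and tested with the quasi-likelihood test of edgeR 4.0.16 (robust fit, group as the sole term, R 4.3.3), with Benjamini-Hochberg adjustment and a threshold of 0.05, separately in each table since the secondary table holds only leftover reads. Fold changes are MYB93 over P19. The standard error is the log2 fold change divided by the square root of the F statistic. CPM is edgeR's cpm value, a count scaled to the tested reads of its library times the TMM factor. Where the P19 group had 0 reads, a bound was computed with 3 reads over the group, and with 1 to 3 reads in a group the ratio is given with an exact 95% interval; both cover counting error only, since reads without molecular identifiers are not independent molecules.

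A total of 34 gene lists was fixed in advance, 18 by Arabidopsis locus and 16 by words in the description. They covered suberin synthesis, export and regulators, cutin and wax, plastid fatty acid synthesis, phenylpropanoids, flavonoids, secondary wall, photosynthesis, defence, jasmonate, abscisic acid, senescence, marker genes of guard cells, vasculature, epidermis and root endodermis, housekeeping genes, and families of enzymes, regulators and structural proteins. A transcript entered a locus list by the locus in its symbol or descriptions, or by the member's symbol; 5 primary and 70 secondary transcripts whose symbol belonged to another gene were left out. Lists were tested on the primary table with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists, and again with a correlation estimated for each list. The planned enrichment of annotation terms was not run, because the deposited annotation columns used here hold no such terms.

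Named transcripts were chosen by a rule fixed in advance. It took every tested transcript annotated MYB93, MYB53 or MYB92; up to 4 called transcripts with the smallest adjusted p per locus list (up to 8 for the suberin and regulator lists), at most 1 per list member, or the most abundant member of a list with no call; and the 10 risen and 5 fallen primary and 3 risen and 3 fallen secondary transcripts with the largest change among annotated ones with a mean of at least 10 CPM in the higher group and groups that did not overlap. Near-identical transcripts with 1 annotation were named once, by the transcript with the most reads.

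The test was tried on simulated data drawn from the real means, dispersions and library sizes, with 200 changed transcripts, over 10 draws. Among 35522 primary transcripts it called 21.6% of 2-fold and 69.7% of 4-fold changes, and 7.6% of its calls were unchanged transcripts. Among 30286 secondary transcripts these shares were 0.2%, 17.1% and 6.2%. Far fewer transcripts changed in the simulation than were called in the data (6734 primary and 1698 secondary). The adjusted threshold is stricter when few transcripts change, so these shares cannot be carried over to the real test. The alternatives fixed before the data were examined were median-ratio and upper-quartile scaling, no filter, a filter of 5 CPM in at least 4 libraries, DESeq2 1.42.0, limma voom, the replicate number as a block, each library left out, counts summed by Arabidopsis symbol, and other list tests. Unique reads, library totals as the sole scaling, lists on the secondary or joined tables, secondary counts summed by symbol, list counts without MYB93 replicate 1, and the regulator list without MYB93-annotated transcripts were added after seeing the data.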

Results

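The design compared N. benthamiana leaves that transiently expressed apple MYB93, a MYB transcription factor that the series title places in suberin deposition, with leaves that received the P19 strain alone. There were 4 libraries per group. In the primary table the MYB93 libraries held 19452036, 16501565, 22351974 and 15348450 reads and the P19 libraries 20404223, 19492233, 18573166 and 18585510. The first principal component, which held 54.2% of the variance, separated the groups. MYB93 replicate 1 stood apart: its mean correlation of log2 CPM with the other 3 MYB93 libraries was 0.913, where the lowest correlation among those 3 was 0.957. No pair within a group was 1 library deposited under 2 names (chi-square per degree of freedom at least 6.58).

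**Figure D1:**
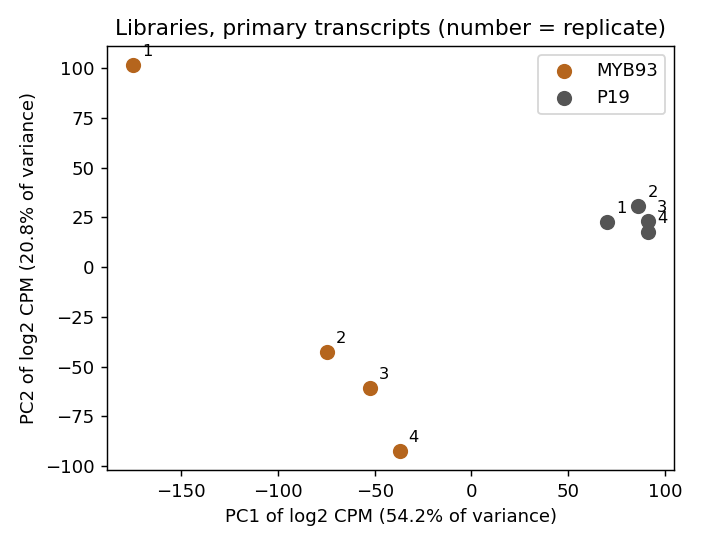
Principal components of log2 CPM over the tested primary transcripts, with PC1 (54.2% of variance) on the x axis and PC2 (20.8%) on the y axis; each point is a library, coloured by group and numbered by replicate. The 4 P19 libraries lie between 70.1 and 91.5 on PC1, and the MYB93 libraries between -174.9 and -37.1, with replicate 1 farthest from the rest.

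Enzymes that build the aliphatic part of suberin rose together in MYB93 leaves. CYP86A1, which hydroxylates the terminal carbon of fatty acids, went from 2.13 ± 1.74 CPM in P19 to 2756 ± 626 CPM in MYB93 leaves (SD, n = 4) in the secondary table (transcript Nbv5tr6408715, log2 fold change 10.32, SE 0.49, and 10.99 without P19 replicate 3). Of its reads, 1051 of 30570 in MYB93 and 7 of 26 in P19 leaves matched a single transcript. CYP86B1, a hydroxylase of very long chains, rose from 5.78 ± 2.31 to 466.7 ± 50.9 CPM (Nbv5tr6237440, 80.6-fold). GPAT5, an acyltransferase that links suberin monomers to glycerol, rose from 29.7 ± 3.04 to 377.7 ± 36.5 CPM (Nbv5tr6238075, 12.7-fold). The fatty acid elongation enzymes followed: KCS2 rose 35.5-fold (Nbv5tr6211563), KCS1 11.6-fold (Nbv5tr6201800), KCR1 7.34-fold (Nbv5tr6204950), PAS2 3.21-fold (Nbv5tr6213323) and CER10 2.79-fold (Nbv5tr6236329). Of 23 tested primary transcripts on the list, 14 rose, 0 fell and 9 did not pass edgeR's test; adjusted over the list alone, 16 rose and 1 fell. The list's median log2 fold change was 1.48 and it stood above other transcripts (camera adjusted p = 4.44e-12; adjusted p = 0.0139 with an estimated correlation, and 0.0578 and 0.0709 without MYB93 replicate 3 and P19 replicate 2). In MYB93 replicate 1 the list's median lay 1.79 above the P19 mean on the log2 scale, against 1.36 to 1.41 in the other 3 MYB93 libraries, and 16 transcripts rose and 1 fell without that library. Among secondary transcripts, 18 of 27 list members rose and 0 fell.

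Transporters that carry suberin monomers across the plasma membrane rose as well. ABCG1 went from 8.15 ± 3.79 to 673.5 ± 230.1 CPM (SD, n = 4; Nbv5tr6236478, 82.5-fold), and ABCG2 rose 46.3-fold (Nbv5tr6220564, log2 fold change 5.53, and 6.35 without P19 replicate 1). ABCG16 rose 29.3-fold (Nbv5tr6206538) and ABCG10 2.79-fold (Nbv5tr6220244). An ABCG23-annotated transcript of the secondary table went from 1.77 ± 0.665 to 609.7 ± 196.6 CPM (Nbv5tr6391581), with 1201 of its 6746 reads in MYB93 leaves matching a single transcript. The lipid transfer protein LTPG2 rose 5.48-fold (Nbv5tr6229932), and a transcript described by the LTPG1 locus but with the symbol AT2G44300 rose 14.8-fold (Nbv5tr6200335, log2 fold change 3.89, and 4.55 without P19 replicate 1). Of 19 tested primary list members, 10 rose and 0 fell; adjusted over the list alone, 12 rose and 0 fell. The list's median log2 fold change was 0.89, also with its 1 transcript that lacked P19 reads at its bound. The camera adjusted p was 1.3e-08, and the adjusted p = 0.0365 with an estimated correlation (0.0125 to 0.0833 when 1 library was left out). Leaving out MYB93 replicate 1 gave 11 risen and 0 fallen. In the secondary table all 7 tested members rose.

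Among MYB factors known from suberin and Casparian strip regulation, the MYB67-annotated transcript rose from 0.22 ± 0.10 to 54.5 ± 7.36 CPM (Nbv5tr6217099, 236-fold). MYB84 rose 16.2-fold (Nbv5tr6218132) and MYB102 3.48-fold (Nbv5tr6235520). MYB41, a factor that can switch on suberin synthesis in leaves, went from 1.46 ± 0.60 to 3.75 ± 1.46 CPM (Nbv5tr6229093, edgeR adjusted p = 0.0354), and that call was lost without either of MYB93 replicates 2 and 4 or without P19 replicate 2, 3 or 4 (adjusted p = 0.059 to 0.102). Of 11 list members 7 rose and 0 fell; adjusted over the list alone, 9 rose and 0 fell. The 11 include 3 MYB93-annotated transcripts, and the transgene is itself a MYB93 sequence; with these 3 left out, 5 of 8 rose and 0 fell (camera adjusted p = 1.59e-05; adjusted p = 0.0439 with an estimated correlation). With all 11 the camera adjusted p was 3.83e-08, and the adjusted p = 0.0484 with an estimated correlation, a call lost whichever of the 8 libraries was left out (0.0565 to 0.0853). Without MYB93 replicate 1, 8 rose and 0 fell.

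Transcripts whose best Arabidopsis match was MYB93 were of 3 primary and 3 secondary kinds. Nbv5tr6235880 rose from 0.94 ± 0.49 to 39.9 ± 9.35 CPM and Nbv5tr6229127 from 1.07 ± 0.05 to 78.9 ± 27.3 CPM (SD, n = 4). Nbv5tr6214655 was at 2.47 ± 1.15 and 3.20 ± 1.24 CPM (log2 fold change 0.37, SE 0.39, edgeR adjusted p = 0.567). In the secondary table Nbv5tr6392390 had 0 reads in the P19 group and 462 in the MYB93 group, at least 170-fold higher with 3 reads over the P19 group as the floor. Nbv5tr6253104 had 1 read against 272, a ratio of 299.8 with a 95% interval from 53.4 to 11880, and Nbv5tr6392391 had 2 against 241, a ratio of 132.8 from 36.4 to 1103. Of these MYB93-group reads, 4, 0 and 0 matched a single transcript. The apple transgene itself is a MYB93 sequence, and the tables hold no separate entry for it.

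**Figure D2:**
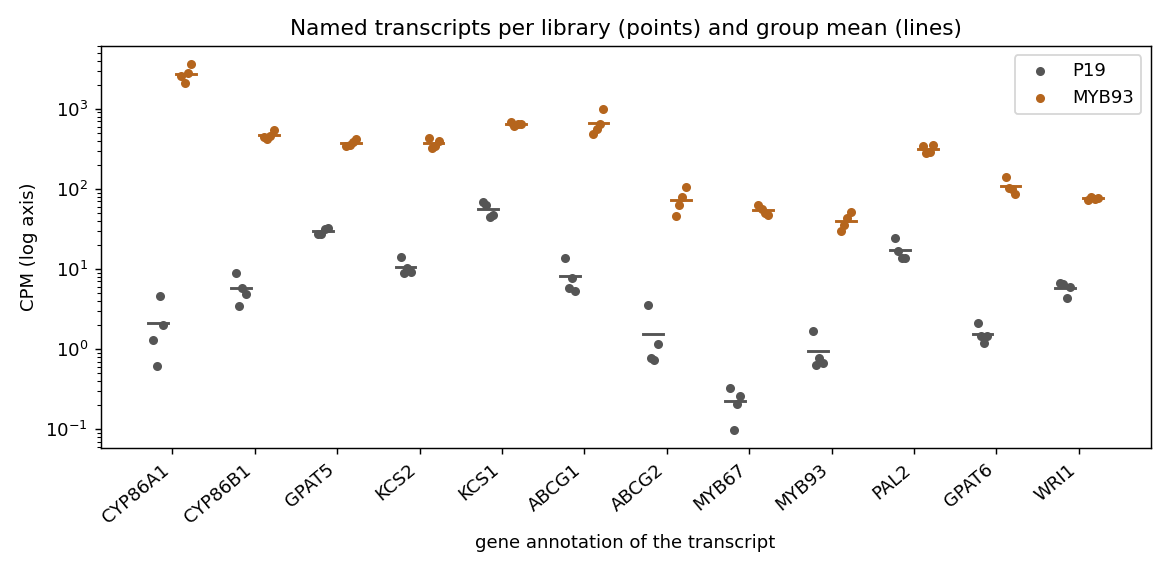
CPM per library on a log axis for 12 named transcripts (x axis, by gene annotation), with P19 in grey and MYB93 in brown; each point is a library and each line a group mean over 4 libraries. CYP86A1 comes from the secondary table and the others from the primary table, so levels are to be compared within a gene; all 4 MYB93 libraries lie above all 4 P19 libraries for each.

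Enzymes of cutin, a related lipid polymer of aerial surfaces, and of wax also rose. GPAT6, which makes cutin precursors, went from 1.57 ± 0.40 to 107.3 ± 23.4 CPM (SD, n = 4; Nbv5tr6218783, 68-fold). CER4, a reductase that makes wax alcohols, rose 26-fold (Nbv5tr6203423) and CER3, of alkane synthesis, 15.4-fold (Nbv5tr6246004). A GPAT4-annotated secondary transcript rose 9.49-fold (Nbv5tr6262210, with 803 of 7380 reads in MYB93 leaves matching a single transcript). Of 24 list members 15 rose and 0 fell, and the same counts held adjusted over the list alone (camera adjusted p = 9.53e-11; adjusted p = 0.0376 with an estimated correlation, and 0.0123 to 0.0965 when 1 library was left out). The counts were 16 and 0 without MYB93 replicate 1, and 18 and 0 of 28 in the secondary table.

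The supply side of fatty acids rose with them. WRI1, a regulator of plastid fatty acid synthesis, went from 5.87 ± 1.01 to 76.0 ± 2.59 CPM (SD, n = 4; Nbv5tr6237694, 12.9-fold). The reductase MOD1 rose 4.44-fold (Nbv5tr6211804) and CAC2, the biotin carboxylase subunit of acetyl-CoA carboxylase, 3.02-fold (Nbv5tr6205586). A KAR-annotated secondary transcript rose 10.7-fold (Nbv5tr6431069). Of 16 list members 13 rose and 0 fell; adjusted over the list alone, 15 rose and 0 fell. The camera adjusted p was 7.15e-11, and the adjusted p = 0.0376 with an estimated correlation (0.0319 to 0.0853 when 1 library was left out). As many, 13, rose without MYB93 replicate 1; among secondary transcripts, 8 rose and 1 fell of 34.

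Phenylpropanoid enzymes, which supply the aromatic part of suberin and lignin, rose in most of their members. PAL2, at the entry of the pathway, went from 17.1 ± 4.89 to 316.5 ± 37.7 CPM (SD, n = 4; Nbv5tr6230676, 18.5-fold). The coenzyme A ligases 4CL1 and 4CL3 rose 33.8-fold (Nbv5tr6215803) and 20.6-fold (Nbv5tr6243580), and CCOAOMT1 rose 5.15-fold (Nbv5tr6226062). Of 25 list members 16 rose and 2 fell; adjusted over the list alone, 18 rose and 2 fell. The camera adjusted p was 1.78e-09, and the adjusted p = 0.0484 with an estimated correlation (0.0416 to 0.109 when 1 library was left out). When MYB93 replicate 1 was left out, 16 rose and 1 fell, and in that library the list's median lay 1.67 above the P19 mean against 0.88 to 1.16 in the other 3. Among secondary transcripts, 2 rose and 0 fell of 7. The 2 fallen members carried a PAL1 (Nbv5tr6207135) and an HCT (Nbv5tr6225344) annotation, and are named here after their values were seen. The flavonoid list held 1 tested transcript, FLS1 (Nbv5tr6236792), at 16.5 ± 6.54 CPM in P19 and 12.5 ± 2.45 CPM in MYB93 leaves (edgeR adjusted p = 0.356).

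Among the 10 risen transcripts with the largest changes, a methyltransferase matched to AT4G35160 rose from 0.17 ± 0.16 to 85.6 ± 21.9 CPM (SD, n = 4; Nbv5tr6214002, log2 fold change 8.89, SE 0.45, and 9.61 without P19 replicate 1), though just 196 of its 6086 reads in MYB93 libraries matched a single transcript. A metal-binding protein matched to AT1G29000 rose with a log2 fold change of 8.59 (Nbv5tr6217989). A set of 5 transcripts was described as cornifin alpha or proteoglycan 4-like (Nbv5tr6227731, Nbv5tr6223217, Nbv5tr6232610, Nbv5tr6206592 and Nbv5tr6235071), with log2 fold changes of 8.53, 8.49, 8.41, 8.25 and 8.16. A CASP-like 1B2 membrane protein rose from 1.32 ± 0.30 to 347.6 ± 95.6 CPM (Nbv5tr6223406), laccase LAC12 from 2.85 ± 1.72 to 725.1 ± 108.5 CPM (Nbv5tr6228735, with 6330 of 50160 reads in MYB93 leaves matching a single transcript), and an uncharacterized protein 260-fold (Nbv5tr6217884). In the secondary table a peroxidase 11 transcript went from 1 read to 909, a ratio of 1002 with a 95% interval from 179.4 to 39620 (Nbv5tr6392208); 100 of the 909 matched a single transcript.

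Of the 5 fallen transcripts with the largest changes, premnaspirodiene oxygenase, a sesquiterpenoid cytochrome P450, went from 108 ± 82.2 to 2.03 ± 1.22 CPM (SD, n = 4; Nbv5tr6228091, log2 fold change -5.72, SE 0.67, and -5.09 without P19 replicate 4). The transcript matched to AT1G23000 fell from 68.6 ± 17.3 to 1.31 ± 0.54 CPM (Nbv5tr6215744), and a secondary transcript with the same match held 128 reads in P19 and 1 in MYB93 leaves (Nbv5tr6341258, a ratio of 0.00861 with a 95% interval from 0.000216 to 0.0488). A GDSL lipase (Nbv5tr6227591), a suberization-associated anionic peroxidase (Nbv5tr6228236) and a mitochondrial small heat shock protein (Nbv5tr6202259) fell with log2 fold changes of -5.49 (-6.51 without MYB93 replicate 3), -5.48 and -5.39 (-6.03 without MYB93 replicate 1). Summed by symbol the peroxidase turned to 1.02 and was called higher. A secondary transcript matched to HIP1, a co-chaperone, went from 226 reads to 3 (Nbv5tr6299416, a ratio of 0.0146 with a 95% interval from 0.00299 to 0.0433); none of these reads matched a single transcript, and with counts summed by symbol it was not called (adjusted p = 0.381). The secondary transcript matched to TDX (Nbv5tr6299418) fell as well, with a log2 fold change of -5.72, or -3.99 without P19 replicate 1 (150 CPM against 6.75 to 24.6 in the other P19 libraries) and -6.41 without MYB93 replicate 3. It was not called by limma voom (adjusted p = 0.218).

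Photosynthesis transcripts were higher in MYB93 leaves, with 28 of 37 risen and 0 fallen (31 and 0 adjusted over the list alone) and a median log2 fold change of 0.84. RCA, the activase of Rubisco, went from 190.0 ± 28.8 to 357.1 ± 45.9 CPM (SD, n = 4; Nbv5tr6234311), and PSAF (Nbv5tr6243753), LHCA4 (Nbv5tr6233248) and LHCB3 (Nbv5tr6203476) rose 2.31-fold, 2.52-fold and 2.48-fold; LHCB3 was not called without P19 replicate 1, 2 or 3 and LHCA4 without P19 replicate 2. The camera adjusted p was 1.84e-09, but the adjusted p = 0.354 with an estimated correlation. In MYB93 replicate 1 the list lay 1.34 above the P19 mean, in the other 3 MYB93 libraries 0.36 to 0.88. The count of risen transcripts was 25 without that library, 5 without MYB93 replicate 2, and 8, 2, 3 and 18 without P19 replicates 1 to 4. In the secondary table edgeR and limma voom called 0 of 27 photosynthesis transcripts and DESeq2 2, both higher, with 9 higher at an unadjusted p under 0.05 (camera adjusted p = 0.00139; adjusted p = 0.138 with an estimated correlation). The description-based photosystem list gave 71 risen of 106 and 0 fallen (85 and 1 adjusted over the list alone; adjusted p = 0.41 with an estimated correlation), with 59 risen without MYB93 replicate 1, 18 without MYB93 replicate 2 and 17, 5 and 8 without P19 replicates 1 to 3; 6 rose and 0 fell of 75 in the secondary table.

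Defence transcripts included 5 that fell and 0 that rose of 15, and the same counts held adjusted over the list alone (camera adjusted p = 0.0312, and 0.227 with an estimated correlation). The list's median lay at -0.58 to -0.29 from the P19 mean in the MYB93 libraries, on the log2 scale. P19 replicate 1 lay within that range, at -0.36, and the other P19 libraries at -0.01 to 0.22. PR4, a pathogenesis-related chitin-binding protein, went from 234.2 ± 71.6 to 56.4 ± 16.9 CPM (SD, n = 4; Nbv5tr6224846) and the salicylic acid marker PR1 from 5.21 ± 3.84 to 0.67 ± 0.34 CPM (Nbv5tr6240267, log2 fold change -2.98, and -2.32 without P19 replicate 4). WRKY70 fell from 171.4 ± 27.2 to 76.5 ± 24.8 CPM (Nbv5tr6220405), and an EDS1 secondary transcript from 13.8 ± 1.23 to 2.92 ± 1.65 CPM (Nbv5tr6392347), a call lost without MYB93 replicate 3. The list call was lost without MYB93 replicate 2 (adjusted p = 0.0519, with 3 fallen), and 7 fell and 1 rose without MYB93 replicate 1; of 13 secondary transcripts 1 rose and 1 fell.

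In the abscisic acid list 7 rose and 2 fell of 16 (8 and 3 adjusted over the list alone; camera adjusted p = 0.0447, adjusted p = 0.407 with an estimated correlation). A transcript with the symbol of ABA2, an enzyme of abscisic acid synthesis, rose 6.61-fold (Nbv5tr6229415). Its descriptions name other enzymes, momilactone A synthase and a secoisolariciresinol dehydrogenase-like protein, and 1952 of its 11870 reads in MYB93 leaves matched a single transcript. ABI5, an abscisic acid response factor, fell from 43.5 ± 5.67 to 7.05 ± 1.46 CPM (SD, n = 4; Nbv5tr6222955). NCED3 (Nbv5tr6227293) and ABF3 (Nbv5tr6230430) had adjusted p-values of 0.0357 and 0.0415 in edgeR and lost the call without several single libraries. ABF3 also lost it with counts summed by symbol (adjusted p = 0.311) and with unique reads (log2 fold change 0.12 against 0.54, adjusted p = 0.785). Without MYB93 replicate 1 the counts were 5 and 4 and the list was no longer called (adjusted p = 0.127), nor without MYB93 replicate 2 or 4 or P19 replicate 2 (adjusted p = 0.126, 0.121 and 0.0615); 4 rose without MYB93 replicate 2 or P19 replicate 3 or 4, and 4 rose with library totals as the sole scaling. Among secondary transcripts, 4 of 23 rose and 0 fell (camera adjusted p = 0.0203; adjusted p = 0.0713 with an estimated correlation). The jasmonate list had 3 risen and 1 fallen of 19 (the same adjusted over the list alone; camera adjusted p = 0.395), with JAZ1 up 2.77-fold (Nbv5tr6204331) and AOS fallen from 11.1 ± 2.13 to 4.08 ± 0.84 CPM (Nbv5tr6231119), a direction that turned with counts summed by symbol (log2 fold change 0.15, adjusted p = 0.562). Senescence had 3 risen and 0 fallen of 7 (the same adjusted over the list alone; adjusted p = 0.109), namely SEN1, up 3.23-fold (Nbv5tr6220627), SAG12, a senescence protease at 0.313 ± 0.105 and 3.26 ± 1.85 CPM (Nbv5tr6207855), and a transcript matched to the chlorophyll breakdown gene NYE1 that a second description calls FIZZY-RELATED 2 (Nbv5tr6221633, 4.03-fold). With counts summed by symbol SAG12 and NYE1 were not called (log2 fold changes of 0.10 and 0.18, adjusted p = 0.892 and 0.542).

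Markers of other cell types did not stand apart as primary lists. Of 12 root endodermis transcripts edgeR called 0 and DESeq2 and limma voom 1 each, with 1 at an unadjusted p under 0.05 (camera adjusted p = 0.446) and SHR at 8.35 ± 1.69 and 9.19 ± 1.56 CPM (SD, n = 4; Nbv5tr6205088). Of 4 guard cell transcripts edgeR, DESeq2 and limma voom called 0, with 1 at an unadjusted p under 0.05 (adjusted p = 0.634) and KAT1 at 80.9 ± 4.84 and 91.6 ± 25.7 CPM (Nbv5tr6218699). Vascular markers had 2 risen of 15 (adjusted p = 0.569), led by VND7, a vessel regulator (Nbv5tr6232005, 3.48-fold), and epidermal markers 1 of 11 (adjusted p = 0.628), PDF1 (Nbv5tr6239806, 2.04-fold), with the epidermal list's median at -0.22 and its mean at 0.18. The secondary wall list had 1 risen of 9 (adjusted p = 0.797), CESA4 (Nbv5tr6206599, 1.95-fold), a call lost without MYB93 replicate 3 or P19 replicate 3 or 4; among secondary transcripts, 3 of 4 members rose, with a median log2 fold change of 3.18 (camera adjusted p = 8.18e-06; adjusted p = 0.0203 with an estimated correlation), and IRX9 rose 44.7-fold (Nbv5tr6394602, with 245 of 907 reads in MYB93 leaves matching a single transcript). These 5 lists had the same counts adjusted over the list alone. Housekeeping transcripts had 1 risen and 3 fallen of 22 (2 and 4 adjusted over the list alone; adjusted p = 0.257), with 1 fallen without MYB93 replicate 2 or P19 replicate 2, 3 or 4 and 5 fallen with library totals as the sole scaling. EF1A fell from 1122 ± 41.2 to 665.3 ± 68.9 CPM (Nbv5tr6233151) and ACT7 rose 1.73-fold (Nbv5tr6233233), a call lost with counts summed by symbol (adjusted p = 0.695). GAPC1 and GAPC2 rose in secondary transcripts (Nbv5tr6394926 and Nbv5tr6319799), the latter a call lost without MYB93 replicate 3 or P19 replicate 2 or 3. Summed by symbol, GAPC1 turned to a log2 fold change of -0.60 and GAPC2 was not called (adjusted p = 0.0588), nor was it with unique reads (0.0607).

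**Figure D3:**
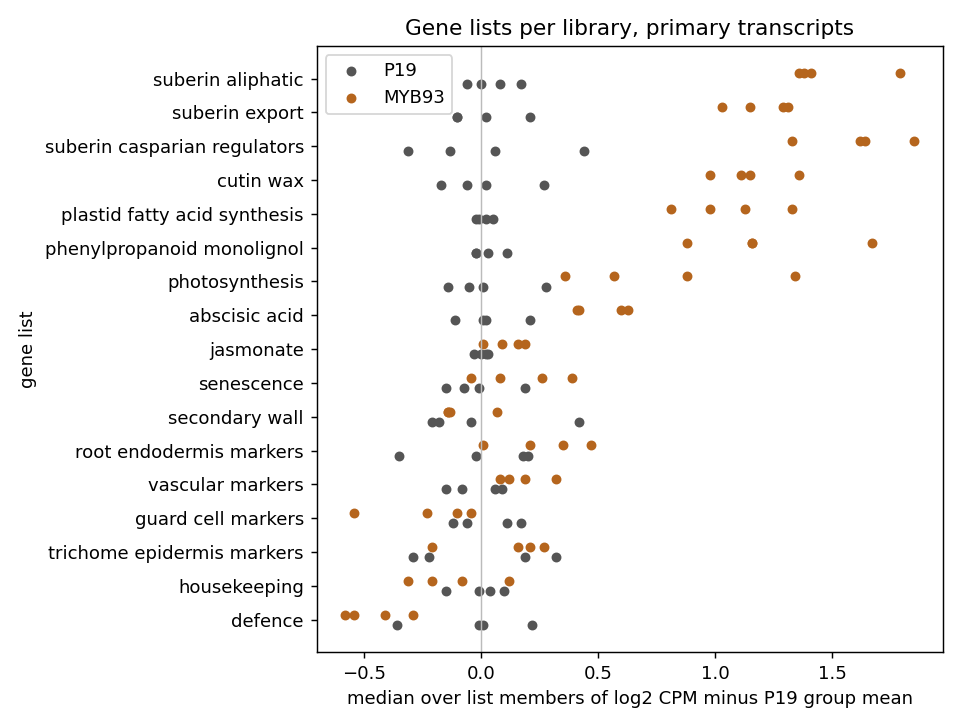
Median over the members of 17 gene lists of log2 CPM minus the mean of the P19 group, per library (x axis, log2 units; y axis, list), with P19 in grey and MYB93 in brown. Suberin synthesis lies between 1.36 and 1.79 in the MYB93 libraries, photosynthesis between 0.36 and 1.34.

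Among families taken by description, lipid transfer proteins had 34 risen and 0 fallen of 63 (37 and 0 adjusted over the list alone; adjusted p = 0.176 with an estimated correlation), ketoacyl-CoA synthases 10 and 0 of 23 (14 and 0; 0.0376), BAHD acyltransferases 14 and 1 of 30 (17 and 1; 0.0484), GDSL lipases 27 and 7 of 101 (29 and 9; 0.0772) and peroxidases 30 and 5 of 91 (33 and 6; 0.164), each p with an estimated correlation and each called by camera with the preset one. Among secondary transcripts of these 5 families, in the same order, 3, 5, 3, 8 and 17 rose and 3, 1, 2, 0 and 0 fell. Histones had 26 risen and 2 fallen of 88 (49 and 2; adjusted p = 0.501 with an estimated correlation), with 12, 11 and 43 risen without MYB93 replicates 2, 3 and 4 and 6, 2 and 6 without P19 replicates 2, 3 and 4. As the sole scaling, library totals gave 17 risen. NAC factors had 27 risen and 12 fallen of 107 (35 and 14; adjusted p = 0.137 with an estimated correlation) and MYB factors 21 and 9 of 127 (22 and 9; 0.0573), a list no longer called without MYB93 replicate 1 or 4 or P19 replicate 3 or 4 (camera adjusted p = 0.0528, 0.0563, 0.0652 and 0.0526). Heat shock proteins had 4 risen and 13 fallen of 63 (7 and 14 adjusted over the list alone, camera adjusted p = 0.584 with an estimated correlation). Their median lay 0.26 above the P19 mean in MYB93 replicate 1 and below it in the other 3 MYB93 libraries (-0.29 to -0.22). P19 replicate 1 lay as high, at 0.28, and the other P19 libraries at -0.16 to 0.06. Without MYB93 replicate 2 the list was not called (camera adjusted p = 0.0502). Among secondary transcripts, 0 heat shock transcripts rose and 13 fell of 122 (camera adjusted p = 2.01e-07; adjusted p = 0.0203 with an estimated correlation). There, 4 histones of 48 rose and 0 fell (0.0203 and 0.395), 8 NAC factors of 72 rose and 5 fell (0.774 and 0.746) and 11 MYB factors of 134 rose and 1 fell (0.0203 and 0.0358). Not called as primary lists were WRKY factors (6 risen and 20 fallen of 99, 7 and 21 adjusted over the list alone), cytochromes P450 (31 and 25 of 157, 34 and 30), laccases (5 and 0 of 34, the same), dirigent proteins (3 and 1 of 10, 4 and 1), terpene synthases (1 and 0 of 8, the same) and ribosomal proteins (29 and 24 of 479, 11 and 18). Their camera adjusted p-values were 0.126, 0.934, 0.0904, 0.514, 0.643 and 0.456. The terpene synthase list does not speak for that whole family. It held none of the 17 fallen transcripts, of 20 tested, annotated as 5-epi-aristolochene synthase, which were looked at after the values were seen. In the secondary table cytochromes P450 were called higher (28 risen and 6 fallen of 120; camera adjusted p = 5.11e-08, adjusted p = 0.0086 with an estimated correlation). WRKY factors were called lower without P19 replicate 1 (0.0366), laccases higher without MYB93 replicate 3 (0.0328) or P19 replicate 1 (0.0225), and ribosomal proteins lower without MYB93 replicate 1 (7.11e-06), where 107 fell. With library totals as the sole scaling 20 ribosomal transcripts rose and 50 fell. The median and mean had opposite signs for cytochromes P450 (-0.05 and 0.12) and terpene synthases (-0.19 and 0.15).

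Over all, 6734 of 35522 tested primary transcripts passed edgeR's adjusted threshold, 4072 risen and 2662 fallen, and 4056 changed at least 2-fold, 2587 up and 1469 down. Among secondary transcripts, 1698 of 30286 passed, 1096 risen and 602 fallen. The groups did not overlap in 9179 of the tested primary transcripts, where chance gives 2.86%. Scaling by library totals alone shifted the median of all primary transcripts by -0.13 on the log2 scale and gave 3288 risen and 3508 fallen. The primary count was 4279 without P19 replicate 3 and 8148 without MYB93 replicate 1; the secondary count was 982, 1062 and 1129 without P19 replicate 3, MYB93 replicate 2 and P19 replicate 2. Of 34 lists, 17 were called higher and 2 lower by camera, and 8 of the 19 held with an estimated correlation. Each of these 8 lost that second call when at least 1 library was left out. All 8 lost it with the replicate number as a block (camera adjusted p = 0.0841 to 0.0941). Both changes leave that test fewer residual degrees of freedom, which raises the p of an equal statistic. The losses alone thus neither show nor exclude that a call rests on 1 library or a batch. The replicate block also ended 7 calls of named transcripts, those of LHCA4, LHCB3, EDS1, CESA4, GAPC2, NCED3 and MYB41 (edgeR adjusted p = 0.0553, 0.0564, 0.0524, 0.0563, 0.055, 0.0598 and 0.0978). Camera with the preset correlation also called 3 to 12 lists in splits of the libraries balanced for group, so its small p-values alone are weak evidence.

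The authors' deposited table of selected transcripts held 374, of which 287 were primary and 87 secondary, 294 higher and 80 lower in MYB93. Of these, 372 were tested and all 372 were called in the same direction; the list was chosen on these same libraries, so this is not independent evidence. The smallest absolute log2 ratio in the authors' deposited table was 3.33.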

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

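The tests of MYB93 replicate 1 (other than that of depth, set after its value was seen in place of thinning to the smallest total, which hardly moved the mean correlation, from 0.913 to 0.915), of photosynthesis and of the transgene were chosen after that library, those lists and those transcripts had been seen and before the values of the tests, but 3 criteria were added after the values were seen, the standard errors and the comparison with each P19 library in the photosynthesis test, the highest correlation in the test of length, and the amount by which a scaling had to move the list; the reading of the authors' list in the splits was also set afterwards. In 15 of 186 groups of 4 libraries, a library lay far from the other 3; chance alone gives about 1 in 20, or 9.3.

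MYB93 replicate 1 had a primary scaling factor of 0.845 against 0.992 to 1 in the other MYB93 libraries. It was also high for KCR1 (346 CPM against 228 to 234), CER10 (148 against 108 to 114) and KAT1 (130 against 73.9 to 83). Its total of 19452036 reads lay within the 15348450 to 22351974 of the other 3, which argues against depth, and with each library's trend on transcript length removed its mean correlation with the other 3 was 0.886 against a lowest of 0.939 among those 3, and its highest single one 0.912, which argues against length as the whole cause. A larger response of the same transcripts met its slope (1.09, against 0.68 to 0.89 in the others) but not its scatter, which was 1.64 times the largest of the others. MYB93 replicate 1 also had reads on fewer primary transcripts, 43315 against 45738 to 46425 in the other 3 MYB93 libraries. Its 10 most abundant transcripts held 5.38% of its reads, against 3.39% to 4.31%. The cause of this was not tested. P19 replicate 1 also had the lowest mean correlation within its group, by a smaller gap (0.960 against 0.967 to 0.972 in the other P19 libraries). The deviations of the 2 libraries numbered 1 from their group means correlated by 0.102. A factor shared by the replicate number and a difference between pools of plants stay open, among other causes, and were not tested.

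Photosynthesis transcripts lay above the median of all transcripts by at least 0.83 on the log2 scale under the 3 planned scalings. A scaling moves all transcripts nearly alike, so it cannot lift the list above the others, and this test could not have come out otherwise. The list's own median was 0.84, 0.83, 0.74 and 0.69 with TMM, median-ratio, upper-quartile and library-total scaling. Those values argue against the choice among these scalings as the cause. Without MYB93 replicate 1 the list's median was 0.59, past the halfway value of 0.42 set in advance and over 2 standard errors between libraries (0.18 each) above 0. The other 3 MYB93 libraries (0.36 to 0.88) lay above each P19 library (-0.14 to 0.28), which argues against that library alone. The margin was narrow: replicate 4 lay at 0.36 in MYB93 and 0.28 in P19, and on the description-based photosystem list at 0.35 and 0.33. Over replicates 1 to 4 the photosynthesis list fell in MYB93 (1.34, 0.88, 0.57 and 0.36). In P19 it mostly rose (-0.05, -0.14, 0.01 and 0.28). The gap between the groups thus narrowed with the replicate number, and the cause of this was not tested. How much of the 0.84 with all libraries came from MYB93 replicate 1 stays open, since 0.59 passed 0.42 by less than 1 standard error. Bacterial dose differed with the group and stays open, as does MYB93 expression itself.

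For the MYB93-annotated transcripts, the smallest ratio of the log2 fold change from unique reads to that from all reads was 0.864 over the called primary transcripts. Reads of the apple transgene could match a single N. benthamiana transcript best, so transgene reads and the plant's own MYB93 transcripts cannot be told apart in these tables.

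Among P19 libraries, replicate 4 stood apart for PR1 (11 CPM against 3.11 to 3.39), RCA (233 against 172 to 178), CAC2 (93.8 against 110 to 113) and SAG12 (0.47 against 0.246 to 0.278). Replicate 1 stood apart for TDX (150 against 6.75 to 24.6), ABCG2 (3.57 against 0.726 to 1.15) and the MYB93-annotated Nbv5tr6235880 (1.67 against 0.638 to 0.778). Single reads or pairs of reads set the rest: Nbv5tr6253104 at 0.338 CPM in P19 replicate 4, Nbv5tr6392391 at 0.657 and the peroxidase 11 transcript at 0.328 in P19 replicate 3, and the secondary AT1G23000 transcript at 0.286 in MYB93 replicate 3, each with 0 in the other libraries of its group.

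Of the 35 splits of the 8 libraries into 4 and 4, 1, the real one, gave as many calls. It gave 6734 primary transcripts (highest other 0), 4056 changed at least 2-fold (highest other 0) and 1698 secondary transcripts (highest other 0). A share of 1 in 35 is the lowest these splits can give, so it argues against a chance difference but cannot exclude one. The other splits mix the groups and the real difference adds to their spread, so their counts of 0 do not measure the distance from chance. The 372 called among the authors' selected transcripts (highest other 0) say nothing on chance, since that list was chosen on the real groups. For gene lists the real split gave 19 and was again 1 of 35, and the highest other, which still set 3 MYB93 against 3 P19 libraries, gave 18. The 18 splits with 2 libraries of each group on each side gave 3 to 12. Camera with the preset correlation thus called lists where the groups were balanced, so such a call is weak evidence by itself.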

How the results depend on the processing

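Unique reads, library totals as the sole scaling, the secondary and joined tables, secondary sums by symbol and the regulator list without MYB93-annotated transcripts were chosen after seeing the data. Median-ratio and upper-quartile scaling, limma voom and unfiltered or unique primary counts kept the primary counts within 1.5 times. Beyond that, the 2-fold primary count was 2672 with the strict filter and 2620 with counts summed by symbol, both of which test fewer features. The secondary count was 2965 without a filter (1784 risen, 1181 fallen), 3081 with DESeq2 (1786 and 1295) and 753 with unique reads (468 and 285), where 9336 transcripts were tested; for the first 2 of these the cause was not tested. Leaving out 1 library gave 4279 to 8148 primary calls (2654 to 4497 risen, 1625 to 3798 fallen) and 982 to 2074 secondary calls (669 to 1271 risen, 313 to 803 fallen), with fewer samples in each fit. With an estimated correlation 8 lists were called instead of 19. Of 645 alternative tests of a list 33 lost the call, 9 gained it, 6 turned direction with a call in at least 1 of the settings compared, and 597 did none of these. The lists of suberin synthesis, suberin export and MYB regulators stayed called in each alternative that changed 1 choice; with an estimated correlation and 1 library left out together, they lost the call for 2, 5 and 8 of the 8 libraries. With all libraries and an estimated correlation all 3 lost it under the replicate block (0.0841, 0.0841 and 0.0858), export also with the strict filter (0.086), and regulators with median-ratio scaling (0.056), library totals (0.0568) and 1 transcript per list member (0.0814). The 6 directions that turned with a call were those of the secondary wall list in the secondary table (adjusted p = 8.18e-06), defence there (0.925), BAHD acyltransferases there (0.76), and cytochromes P450 there (5.11e-08), in both tables joined (0.028) and by fry (0.0151); the cause was not tested. Uncalled lists turned as well, in the secondary table jasmonate, vascular, epidermal, housekeeping and laccase, and under other alternatives secondary wall, cytochromes P450, ribosomal, dirigent and guard cell lists. Of 85 named transcripts 81 were called, and 13 lost the call under at least 1 alternative, 8 of them without 1 library and 7 under the replicate block. An uncalled one, 1 in all, gained a call. When summed by symbol 3 changed sign: Nbv5tr6394926 (-0.60), Nbv5tr6231119 (0.15) and Nbv5tr6228236 (1.02), sums that join other transcripts.

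The labels number the replicates of both groups but do not say that a number marks a shared batch. Deviations from the group means correlated by 0.102, 0.064, 0.067 and 0.066 in the primary table, where 1 of 4 pairs passed 0.1. In the secondary table they correlated by 0.079, 0.046, 0.048 and 0.058. These correlations were low, so the main test did not pair the samples by number. Yet every library correlated best with its own number in both tables (highest other 0.06 and 0.041), so a shared batch stays open. With the replicate block 6090 primary, 1209 secondary and 3634 risen primary transcripts were called. In the secondary table, with its own depth and spread, the simulation with just 200 changed transcripts recovered 17.1% of 4-fold changes. Depth and spread were not tested apart.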

Other observations

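The gene families below were taken from the descriptions after the values were seen, among 23 families looked at, and have no test of their own. Sesquiterpene synthases annotated as 5-epi-aristolochene synthase, which make the precursor of the Nicotiana phytoalexin capsidiol, fell in 17 of 20 tested primary transcripts and rose in 0, with a median log2 fold change of -2.46; 15 to 17 fell when 1 library was left out. Premnaspirodiene oxygenases, sesquiterpenoid cytochromes P450, had 12 fallen and 2 risen of 25. Glutathione S-transferases had 25 fallen and 7 risen of 68. Proteins described as cornifin alpha or proteoglycan 4-like rose in 11 of 12, with a median of 7.88, and in 11 whichever library was left out. Xyloglucan endotransglucosylases, which remodel the cell wall, had 21 risen and 1 fallen of 39, aquaporins 21 and 1 of 47, and CASP-like membrane proteins 9 and 4 of 51. Leaving out 1 library gave 19 to 21 risen xyloglucan endotransglucosylases, 13 to 21 risen aquaporins (13 without MYB93 replicate 2 or P19 replicate 2 or 3, 14 without P19 replicate 4), 7 to 10 risen and 2 to 4 fallen CASP-like proteins, 23 to 29 fallen glutathione S-transferases and 10 to 14 fallen premnaspirodiene oxygenases. Each of these medians kept its sign under TMM, median-ratio, upper-quartile and library-total scaling.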
